A study of Mus musculus with 12 samples.

How the data were processed

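Polyadenylated RNA from 12 samples of mouse CD8 T cells was sequenced from stranded libraries, per the labels' protocols. The labels place 3 samples in each of 4 media: IMDM (Iscove's modified Dulbecco's medium), IMDM with physiologic carbon sources, VIM, and VIM with physiologic carbon sources. The carbon sources were acetate, beta-hydroxybutyrate, citrate, lactate and pyruvate, and cells were kept in each medium for 24 h before RNA was taken. The labels number the samples of each medium 1 to 3 and do not say whether these came from separate mice or cultures.

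Trim Galore 0.6.0, STAR 2.7.8, edgeR and the mm10 genome are named in the submitters' processing notes. The role and settings of each tool, the annotation release and the rule by which genes were kept are not given in the sources used here. One expression table of the whole series was deposited, with an Ensembl gene ID, a symbol and an NCBI gene number per row, per the file headers, and 12 columns of values whose range, with negative values and a common floor, is that of a log2 scale.

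The 12 value columns carry laboratory codes that occur in no title, description, characteristic or protocol of the samples. A column could therefore be given to a sample or a medium only by its place in the table or by its values, and neither was used. Apart from the range given here, the values of all 12 columns were left out of every step. No comparison between media, fold change, library depth or replicate spread is reported, and the limma models and gene list tests that had been fixed before the data were examined were not run. The series' counts per sample and library totals were not analysed here, so depth is unknown and no interval that needs it is given.

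The identity of the listed genes was analysed instead. Ensembl IDs without version were matched to the GENCODE vM21 annotation of GRCm38, the assembly also called mm10, and 13766 of the 13778 IDs were found. Coordinates are from that annotation and are 1-based. A gene is called listed where its Ensembl ID or its symbol is a row of the table. A listed gene passed the authors' unstated rule for keeping genes over the series as a whole. A gene that is not listed was not shown to be silent, since the rule is unknown and rows may be absent for other reasons.

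Of the gene lists fixed before the data were examined, all 31 were used here for membership. The share of members listed was compared with that of the other protein-coding genes by a 2-sided Fisher's exact test per list with at least 5 protein-coding members, with Benjamini-Hochberg adjustment over the 31 lists and a threshold of 0.05 (SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6, Python 3.11.15). Genes share lists and regulation and are not independent replicates. On simulated data over 21992 protein-coding gene names, the test called 2 of 200 lists of 20 genes drawn at random. Lists with 19 of 20 genes on one side were called in both directions, which their make-up alone ensures, and smaller lists such as the B cell and erythroid ones were not simulated.

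The rule for named genes had several parts. Those on the largest fold changes, on the smallest adjusted p values of the interaction and on list members by p-value need the value columns and named nothing. The last part named 25 genes whatever their values, and these are reported here as listed or not listed, with other list members named as examples. A few of these genes are not reported here by name. The gene families and the mitochondrial genes followed in detail were chosen after the table's rows had been seen. For each mitochondrial protein-coding gene, every word of 50 bases of its transcript was sought on both strands of all GENCODE vM21 transcripts of genes outside the mitochondrial genome, and the percent of words found was compared between listed and unlisted genes by an exact permutation test. Words of 30 and 100 bases were tried as alternatives.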

Results

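The series was built to ask how the supply of physiologic carbon sources changes gene expression in activated CD8 T cells, the cytotoxic lymphocytes. Mouse cells activated through CD3 and CD28 with the growth cytokine interleukin-2 were moved for 24 h to IMDM or VIM medium, each with or without acetate, beta-hydroxybutyrate, citrate, lactate and pyruvate. The 4 media had 3 samples each, 12 in all, in a 2 by 2 layout. The table of the series lists 13778 genes for the series as a whole, and its 12 value columns could not be assigned to samples from the labels and were not used here. The effect of the carbon sources in IMDM, their effect in VIM, the differences between the media and the interaction were therefore not measured. What follows describes which genes the table holds.

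The table listed every gene of the lists for CD8 T cell identity, glycolysis and the TCA cycle. Among markers of other cells, 1 of 8 B cell genes and none of 6 erythroid genes were listed, against 5 of 5 CD4 and regulatory T cell genes. Protein-coding genes made up 81.8% of the listed genes found in the annotation, and 11265 of the 22028 annotated protein-coding genes were listed (51.1%). Processed pseudogenes were the next largest class, with 989 of 9941 listed. Long intergenic RNAs had 281 of 5854 listed. Of the 13778 rows, 12319 had a symbol and an NCBI gene number and 1459 had neither. Over all 31 gene lists, 521 of 577 distinct genes were listed. A listed share above that of other protein-coding genes passed the threshold for 23 lists and a lower one for 2, by Fisher's exact test with Benjamini-Hochberg adjustment. With all annotated genes as the background, these numbers were 27 and 0. Most lists hold genes of T cells, metabolism or growth, so a high share could follow from the choice of lists alone. Membership was taken over the whole series and says nothing about the media, and a listed gene does not show that its programme was active.

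**Figure D1:**
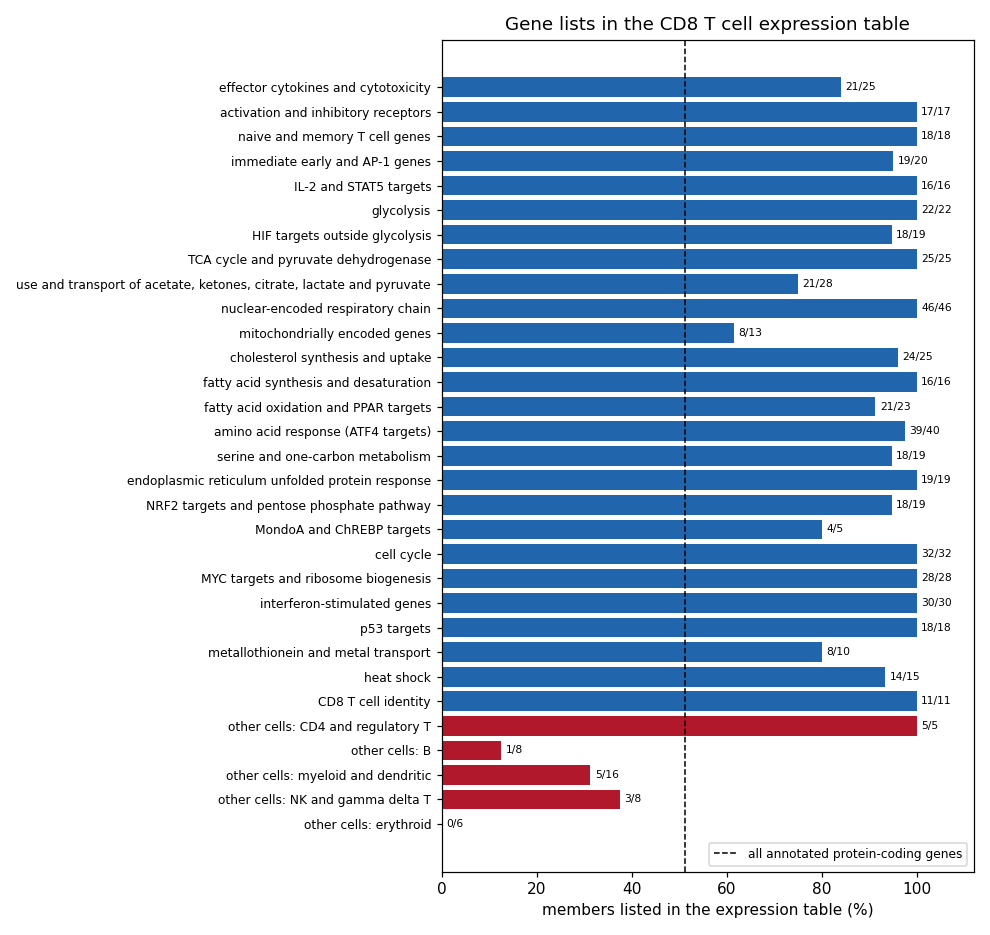
Horizontal bars give the percent of each gene list's members that the expression table lists, with the number listed over the number in the list beside each bar. Blue bars are functional and CD8 T cell lists and red bars are markers of other cell types. The dashed line is the 51.2% of all annotated protein-coding gene names that are listed. The glycolysis, TCA cycle, respiratory chain and CD8 identity bars reach 100%, while the B cell bar ends at 12.5% and the erythroid bar at 0%.

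The list for CD8 T cell identity, which also holds T cell genes not particular to CD8 cells such as Cd3e, was listed in full. The CD8 identity list had 11 of 11 members listed, including Cd8a and Cd8b1, the chains of the CD8 co-receptor, and Cd3e, a signalling chain of the T cell receptor (Fisher's exact test, adjusted p = 0.00144). All 17 genes of the activation and inhibitory receptor list were listed, among them Pdcd1, which encodes the inhibitory receptor PD-1, and Il2ra, the alpha chain of the interleukin-2 receptor. All 18 genes of the naive and memory list were listed, including the transcription factor gene Tcf7 (chromosome 11, 52252371 to 52283014, minus strand). The list of interleukin-2 and STAT5 targets had 16 of 16 listed, and that of immediate early and AP-1 genes had 19 of 20, without Fosb.

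Of the effector genes, 21 of 25 were listed (Fisher's exact test, adjusted p = 0.00144). Ifng, which encodes interferon gamma (chromosome 10, 118441046 to 118445892, plus strand), Gzmb, the protease granzyme B (chromosome 14, 56258838 to 56262260, minus strand), Prf1, the pore-forming perforin (chromosome 10, 61297833 to 61304680, plus strand), and Tnf (chromosome 17, 35199381 to 35202007, minus strand) were among them. Il2, the interleukin-2 gene (chromosome 3, 37120523 to 37125959, minus strand), was not listed, nor were Il3, Gzmf and Gzmg. Il2 was the one gene not listed among the 25 named in advance. In the granzyme family as a whole, 7 of 10 annotated genes were listed.

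The table held most genes of the list for transport and use of the supplied carbon sources. Of the 28 genes for transport and use of acetate, ketone bodies, citrate, lactate and pyruvate, 21 were listed (Fisher's exact test, adjusted p = 0.0174). For lactate and pyruvate, these included the monocarboxylate transporter genes Slc16a1 (chromosome 3, 104638668 to 104658462, plus strand) and Slc16a3 (chromosome 11, 120948480 to 120960868, plus strand), and the lactate dehydrogenase genes Ldha (chromosome 7, 46841475 to 46855627, plus strand) and Ldhb (chromosome 6, 142490249 to 142507957, minus strand). Mpc1 and Mpc2, the subunits of the mitochondrial pyruvate carrier, were listed. For beta-hydroxybutyrate, Bdh1, which encodes its mitochondrial dehydrogenase (chromosome 16, 31422280 to 31458901, plus strand), and Oxct1, which encodes the CoA transferase of ketone body oxidation (chromosome 15, 4026383 to 4155344, plus strand), were listed, whereas Bdh2 was not. For acetate, Acss1, the mitochondrial acetyl-CoA synthetase (chromosome 2, 150618105 to 150668500, minus strand), and Acss2, the cytosolic and nuclear one (chromosome 2, 155517948 to 155585724, plus strand), were listed and Acss3 was not. For citrate, Acly, which cleaves cytosolic citrate to acetyl-CoA (chromosome 11, 100476353 to 100528000, minus strand), and the mitochondrial citrate carrier gene Slc25a1 were listed, and the plasma membrane carrier genes Slc13a3 and Slc13a5 were not.

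The families of these genes were counted beside the 51.1% of all protein-coding genes that were listed. Of 14 annotated Slc16a monocarboxylate transporter genes, 6 were listed, and Slc16a7 was not. Of 5 lactate dehydrogenase genes, Ldha and Ldhb were listed and Ldhc, Ldhd and Ldhal6b were not. Pdk1, Pdk2 and Pdk3, kinases that inhibit pyruvate dehydrogenase, were listed and Pdk4 was not. None of the 5 Slc13a sodium-coupled carboxylate transporter genes was listed. Of 12 Slc2a hexose transporter genes, 5 were listed, including the glucose transporter genes Slc2a1 and Slc2a3. These counts were not tested against other families.

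Each of the 3 nuclear lists of core energy metabolism was listed in full. All 22 genes of the glycolysis list, all 25 genes of the TCA cycle and pyruvate dehydrogenase, and all 46 nuclear-encoded respiratory chain genes were listed, with adjusted p values of 2.38e-06, 3.59e-07 and 1.41e-12 by Fisher's exact test. In contrast, 8 of the 13 protein-coding genes of the mitochondrial genome were listed, a share that did not differ from that of other protein-coding genes by Fisher's exact test (adjusted p = 0.582). mt-Nd1, mt-Nd2, mt-Nd3, mt-Nd4, mt-Nd5, mt-Nd6, mt-Co1 and mt-Cytb were listed, and mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l were not.

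**Figure D2:**
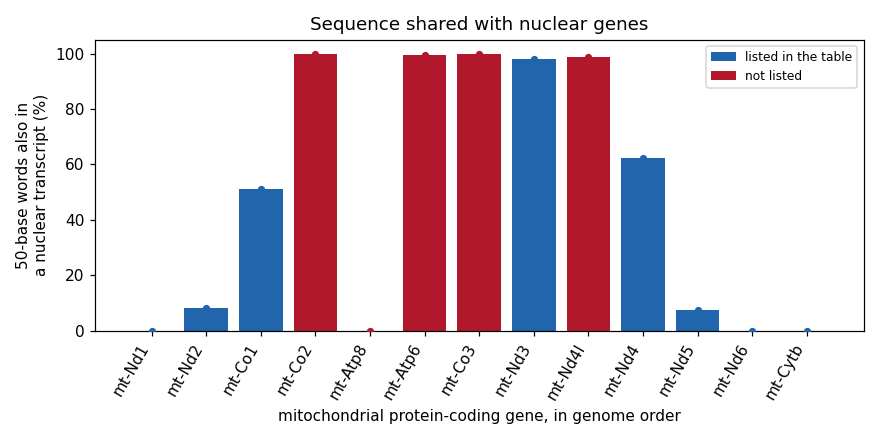
Bars with end points give, for each of the 13 mitochondrial protein-coding genes in genome order, the percent of its words of 50 bases that also occur in an annotated nuclear transcript. Blue genes are listed in the table and red genes are not. mt-Co2, mt-Atp6, mt-Co3 and mt-Nd4l lie between 98.8% and 100%, mt-Atp8 is at 0%, and the listed mt-Nd3 is at 98.0%.

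Most genes of the lipid and stress lists were also listed. Of 25 genes of cholesterol synthesis and uptake, 24 were listed, including Hmgcs1 (chromosome 13, 119690379 to 119708260, plus strand). All 16 genes of fatty acid synthesis and desaturation were listed, as were 21 of 23 of fatty acid oxidation and PPAR targets, without Pdk4 and Acot1. The amino acid response list had 39 of 40 listed, including the asparagine synthetase gene Asns (chromosome 6, 7675169 to 7693254, minus strand) and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase (chromosome 14, 55540266 to 55551242, plus strand). Serine and one-carbon metabolism had 18 of 19 listed, HIF targets outside glycolysis 18 of 19, NRF2 targets and the pentose phosphate pathway 18 of 19, heat shock genes 14 of 15, and the unfolded protein response 19 of 19. Txnip (chromosome 3, 96557957 to 96561883, plus strand) and Arrdc4 (chromosome 7, 68736995 to 68749241, minus strand), glucose-responsive arrestin-family genes, were among the 4 of 5 MondoA and ChREBP targets listed (Fisher's exact test, adjusted p = 0.388). Against other protein-coding genes, a list of 5 genes was too small to pass the threshold with a higher share, even with every member listed. Metallothionein and metal transport genes had 8 of 10 listed (Fisher's exact test, adjusted p = 0.127).

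All 32 cell cycle genes, among them the proliferation marker Mki67 (chromosome 7, 135689784 to 135716361, minus strand), and all 28 genes of MYC targets and ribosome biogenesis, with Myc itself (chromosome 15, 61985391 to 61990374, plus strand), were listed. The 30 interferon-stimulated genes and the 18 p53 targets were also listed in full.

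Of the 5 lists of markers of other cell types, those of B cells and erythroid cells passed the threshold with a listed share below that of other protein-coding genes. The other lists passed it in neither direction. With all annotated genes as the background, 0 lists passed the threshold with a lower share. Of the 55536 annotated genes, 13766 are listed. At that share, lists of 8 and 6 genes could not have passed with a lower share, even with no member listed. The wider background is therefore no check of either call. Of 8 B cell markers, 1 was listed, Cd79b (Fisher's exact test, adjusted p = 0.0432). None of the 6 erythroid genes was listed (Fisher's exact test, adjusted p = 0.0174). Of 16 myeloid and dendritic genes, 5 were listed (Fisher's exact test, adjusted p = 0.145). These were Cd68, Mpeg1, H2-Aa, H2-Ab1 and Cd74, while Lyz2, Csf1r and Itgam were among those not listed. Of 8 natural killer and gamma delta T cell genes, 3 were listed, Klra7, Trdc and Trgc1. The gamma delta genes Trdc and Trgc1 did not enter the test. Of the 6 protein-coding genes tested, 1 was listed (Fisher's exact test, adjusted p = 0.129). The CD4 and regulatory T cell list had 5 of 5 listed, including Cd4 and Foxp3 (Fisher's exact test, p = 0.0628, adjusted p = 0.0749). This is the highest share possible, so the test against other protein-coding genes could not have called a higher share for a list of 5 genes. A listed marker gives no level, so the share of such cells in any sample was not measured.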

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

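None of the alternatives fixed before the data were examined was run, because each needs the 12 value columns, which match no label. No paired analysis was possible because the columns carry no replicate number. The alternatives given here were chosen after seeing the data. Matching by Ensembl ID alone found 520 of the list genes and matching by symbol alone 512, against 521 by either. With all annotated genes as the background in place of protein-coding genes, 27 lists against 23 passed the threshold with a higher listed share. Some lists not called against protein-coding genes were therefore called with the wider background, and the lack of a call for them rests on the narrower one. With a lower share, 0 lists against 2 passed the threshold. The calls for B cell and erythroid markers rest on the narrower background, of which a larger part is listed. The wider background could not test them, since lists this small could not pass there with a lower share, even with no member listed. The percent of shared sequence in unlisted minus listed mitochondrial genes was 47.1 percentage points with words of 30 bases, 51.2 with 50 and 55.4 with 100, with exact permutation p values of 0.0536, 0.0552 and 0.0326, so only the longest words passed the 0.05 threshold. The genes are not independent in these tests, since most of their closest copies lie side by side on chromosome 1.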

Other observations

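Among antigen receptor genes, all 8 T cell receptor constant genes, 53 of 108 alpha chain V genes and 20 of 22 beta chain V genes were listed, while none of 113 immunoglobulin heavy V genes and none of 100 kappa V genes was. Of 13 immunoglobulin constant genes, 2 were listed. These counts were not tested. Of the 84 annotated cytosolic ribosomal protein genes, 82 were listed, and Rpl3l and Rpl10l were not. Xist, the X inactivation transcript, was listed, and none of the 4 Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y was.

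The tests in this part were chosen after the rows of the table had been seen. mt-Co2, mt-Atp8, mt-Atp6 and mt-Co3, neighbours between positions 7013 and 9390 of the mitochondrial genome, and mt-Nd4l, at 9877 to 10173, were not listed, while Gm28661, Gm10925 and Gm28437, pseudogenes on chromosome 1 between 24613189 and 24615565 with the closest sequence to mt-Co2, mt-Atp6 and mt-Co3, were. Gm10222, the closest copy of mt-Nd4l, was not listed either. Overlap between neighbouring mitochondrial genes is argued against as the whole cause, since mt-Co2 is overlapped over 0% of its length. Reads shared with the nuclear copies are a candidate explanation. Of the words of 50 bases in mt-Co2, 100% also occur in a nuclear transcript, as do 99.5% of those in mt-Atp6, 99.9% in mt-Co3 and 98.8% in mt-Nd4l. The mean over the 5 unlisted genes was 79.6% ± 44.5 (SD, n = 5) against 28.4% ± 37.3 (SD, n = 8) in listed ones, a difference of 51.2 percentage points (2-sided exact permutation test over 1287 arrangements, p = 0.0552). The closest copies of mt-Co1, mt-Co2, mt-Atp6, mt-Co3, mt-Nd3, mt-Nd4l and mt-Nd4 lie side by side on chromosome 1, between 24611535 and 24616197. The genes are therefore not independent in this test. Several values keep the explanation by shared reads open. mt-Co1 and mt-Nd4 were listed together with their closest copies Gm29216 and Gm28439, with 51.1% and 62.2% of their words in nuclear transcripts. Further, mt-Nd3 was listed although 98.0% of its words occur in Gm28438, itself listed, and mt-Atp8 was not listed although 0% of its words occur in a nuclear transcript, and nuclear sequence outside annotated transcripts was not searched. No biological explanation was tested, and levels of mitochondrial genes and of these pseudogenes in the table are best treated as uncertain.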
